A study of Mus musculus with 2 samples.

How the data were processed

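RNA from laser-microdissected tissue of mouse embryos at embryonic day 10.5 was measured on Affymetrix Mouse Gene 2.0 ST arrays, per the series design. Per the labels' protocols, tissue was cut from 20 µm cryosections, and 200 to 1000 pg of total RNA was amplified with a single-primer isothermal method before hybridisation. Amplification from such amounts can lose or over-represent transcripts at random, which no later step can correct. The deposited values are log2 expression values, 1 per gene and array; the submitters' processing notes name Affymetrix Expression Console and RMA, which corrects background, quantile-normalizes probes and summarises them by median polish. Versions, the genome build, the probe annotation used and which arrays were normalized together are not given in the sources used here. The sorted values of the 2 columns differed by at most 0.377, so the arrays had similar but not identical distributions after summarising. No probe-level file or detection call was used, so signal over background is known only through the level of genes thought silent.

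The table held 25429 features, each named by an Entrez gene number. The platform annotation gave exactly 1 symbol for 24675 features, several for 0 and none for 754; the last were left out. All 24675 symbols were found by gene number in a reference table of the GRCm38.p6 assembly and none had changed. No coordinates are given, because the build behind the probe annotation is not stated. No symbol was carried by more than 1 feature. The planned comparison of features of the same gene, meant as a measure of error, and the alternatives on how to combine features therefore could not be run.

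Each array was assigned to its tissue by its title. The comparison was the log2 difference, ventral minus dorsal. With 1 array per tissue there was no test, and the genes below were chosen by size. A gene was kept if the higher of its 2 values reached the floor, the median over all genes of the mean of both arrays, 3.10; this left 13982 genes, 11925 of them protein-coding. Genes at least 2-fold apart were counted on the measured values. The 95th and 99th percentiles of 1365 olfactory and vomeronasal receptor genes over both arrays, 3.92 and 5.48, were taken as marks of background; this reference was chosen after seeing the data. Where the lower array was under the 95th percentile, the printed fold is a lower bound, the brighter value against that percentile, and no fold is printed where both arrays were under it.

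Before the data were examined, 37 gene lists were fixed for the cell types and pathways of this region, along with markers of blood, liver, gut, nerve and muscle that a dissected piece could hold and lists for handling and housekeeping. They named 649 genes, of which 611 were measured and 449 kept. The median difference of each list was set among those of 10000 random lists of equal size, drawn from kept genes outside the list and matched on the mean of both arrays in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. The 1 list with fewer than 3 kept members, sex-linked genes, got no percentile. List medians are given relative to the median of all kept genes, -0.12. The genes named in the text were chosen by a rule fixed at the same time: the 12 with the greatest difference in each direction, leaving out predicted, unnamed, small noncoding and receptor-family genes; up to 4 members of each list with the greatest differences; and 18 genes of interest whatever their values. Some further list members were named to illustrate a level, to complete a small count or to set beside a related gene. They were 3 embryonic globins, Gfi1b, Sparc, Fn1, Vcan, Lhx2, Gapdh, Id1, Id2, Id4 and 3 Y-linked genes, chosen after their values were seen.

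The same steps were tested on simulated differences for the 13982 genes of this comparison, drawn from normal distributions with the robust spread of the real differences at each level. Changes of 1.5, 2 and 3 on the log2 scale were counted as at least 2-fold in the right direction for 84.0%, 94.0% and 100% of changed genes, and 9.10% of unchanged genes were also counted. Of 100 simulated lists of 14 genes, 3 stood apart with no shift, 90 with a shift of 0.5 and 100 with a shift of 1. The simulated genes varied independently and list members were drawn at random, so these shares need not hold for real lists of related genes. Alternatives covered quantile normalization of the columns, centring, a loess on level (span 0.3), other floors, other fold thresholds, means in place of medians, and other ways to draw random lists. A loess on genomic span, random lists matched on span and a floor at the receptor genes' 99th percentile were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.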

Results

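Gene expression was measured in mouse embryos at embryonic day 10.5, in tissue taken above and below the dorsal aorta. The aorta-gonad-mesonephros region, of which this vessel is part, is where the first hematopoietic stem cells of the embryo arise, and the series concerns the tissue under the aorta as a niche for these cells. The comparison was between the ventral piece, cut from under the vessel, and the dorsal piece, cut from between its roof and the notochord, both from the same C57BL/6 embryos, whose number is not given in the sources used here. The later stages that the series design names were not analysed here. There was 1 array per tissue, each given as biological replicate 4, so no difference below has a replicate check, an error or a p-value. Expression values ran from 1.45 to 14.1 on the log2 scale in the dorsal array and from 1.47 to 14.2 in the ventral array, with medians of 3.15 and 3.03. A median this low means that most genes lay near background: 1365 olfactory and vomeronasal receptor genes, which serve here as a reference for genes that these tissues would not be thought to transcribe, had medians of 2.40 and 2.28. The 95th percentile of these receptor genes over both arrays was 3.92, and a level under it is called background here. A fold whose lower level lies between it and the 99th percentile, 5.48, is less certain. Of 24675 genes with a symbol, 5975 lay above it in the dorsal and 5884 in the ventral array. With 2 arrays, the number of arrays limits the precision of every value.

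Tissue under the aorta was compared with tissue above it, gene by gene and by lists of genes. Ptn, which encodes the heparin-binding growth factor pleiotrophin, was 108-fold higher in ventral tissue, at 10.73 against 3.98 on the log2 scale, the dorsal level lying just above background. Among other members of the gene lists, Postn, which encodes the matrix protein periostin, was 19.1-fold higher there, and Bmp5, a bone morphogenetic protein, 17.2-fold. In the opposite direction, Cxcl12, the chemokine that retains hematopoietic progenitors in their niches, was 11.5-fold higher in dorsal tissue, at 10.96 against 7.44, and Ptch1, the receptor and transcriptional target of Hedgehog signalling, 9.32-fold. Of 13982 genes kept for the comparison, 1320 were at least 2-fold higher in ventral and 682 at least 2-fold higher in dorsal tissue, while 11980 lay within 2-fold. These counts are by size alone. The 2002 genes at least 2-fold apart make up 14.3% of the kept genes. In values simulated with the robust spread of these same differences, 9.10% of genes given no added change were at least 2-fold apart. That spread already holds any difference of tissue, so the 9.10% is not a measure of error and the 2 shares do not separate change from noise. Among the 1365 receptor genes, most of them lower in level, 17 were at least 2-fold apart. Of the kept genes that exceeded the receptor genes' 99th percentile, 5.48, on at least 1 array, 792 were at least 2-fold higher in ventral and 335 in dorsal tissue. Over the kept genes the median difference, ventral minus dorsal, was -0.12. With the differences centred on that median the counts became 1527 and 527, so that the share of higher values in ventral tissue went from 65.9% to 74.3%. Quantile normalization of the 2 columns moved that share the other way, with counts of 1157 and 799. Across the kept genes, which are not independent replicates, the arrays had a Pearson correlation of 0.831 and a Spearman correlation of 0.721. Over the 2628 genes above the receptor genes' 99th percentile on at least 1 array, these were lower, at 0.602 and 0.507. Of those genes 42.9% were at least 2-fold apart, although a choice by the higher array in itself favours genes with a gap.

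**Figure D1:**
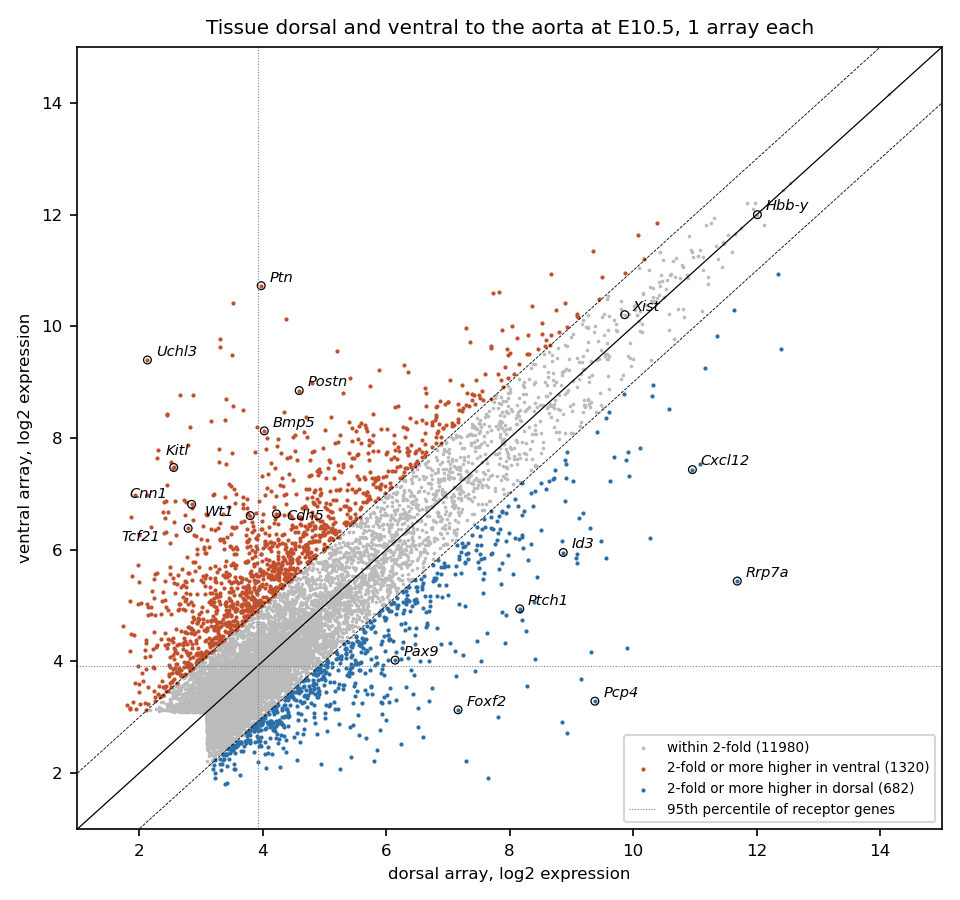
Log2 expression of each of the 13982 kept genes on the dorsal array (x axis) and the ventral array (y axis), with 1 point per gene; the solid line marks equality, dashed lines a 2-fold difference and dotted lines the 95th percentile of the receptor genes, 3.92. Ptn, Postn and Bmp5 lie far above the line, Cxcl12, Ptch1 and Id3 below it, and the embryonic globin Hbb-y close to it at 12.01 on the dorsal array.

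The 12 named genes with the greatest excess in ventral tissue were Uchl3, Ptn, Rab4a, Bnip2, Zdhhc2, Hdac1, Ss18l2, Katnbl1, Trappc6b, Setdb2, Lyrm4 and Selenos. Uchl3 is a ubiquitin hydrolase, Rab4a a small GTPase of endosomes, Trappc6b a subunit of a vesicle tethering complex and Hdac1 a histone deacetylase. Uchl3 was measured at 9.40 in ventral and 2.14 in dorsal tissue. Since the dorsal value was at background, the difference is a bound of at least 44.6-fold. The dorsal value was likewise at background for Rab4a, at least 47.6-fold higher in ventral tissue, for Hdac1, at least 29.0-fold, and for every other gene of the 12 except Ptn and Ss18l2. The 12 with the greatest excess in dorsal tissue were Rrp7a, Btbd35f1, Pcp4, Rps19bp1, Tle5, Efna2, Lin52, Rpain, Foxf2, Rps15a-ps6, Rbm4 and Ssr3. Rrp7a, a ribosome biogenesis factor, was 75.9-fold higher at 11.69 against 5.44, and Efna2, an ephrin ligand, 35.2-fold. Pcp4, which encodes a calmodulin-binding peptide, was at least 44.1-fold higher and Tle5, a Groucho-family corepressor, at least 37.5-fold. Btbd35f1 belongs to a multigene family, Rbm4 has a close paralog and Rps15a-ps6 is a pseudogene, so probes for these genes may also read their relatives and the values are uncertain.

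Genes of the coelomic epithelium and gonadal ridge, which line the body cavity beside the ventral piece, were higher in ventral tissue as a group. Of 14 kept members, 4 were at least 2-fold higher there. Tcf21, a transcription factor of visceral mesenchyme, was at least 5.52-fold higher at 6.38 against 2.79, and Wt1, the Wilms tumour transcription factor of coelomic epithelium, at least 6.46-fold at 6.61 against 3.80. Emx2 and Podxl, the other two, were at least 1.92-fold and 1.38-fold higher, with dorsal values at background. Gata4, at 4.51 against 3.89, and Aldh1a2, the retinaldehyde dehydrogenase, at 4.50 against 3.56, were within 2-fold. The 1 member at least 2-fold higher in dorsal tissue on measured values, Lhx2, was singled out after its values were seen; both of its levels, 3.87 and 2.83, were at background. The median of the list lay 0.93 above that of all kept genes on the log2 scale, at percentile 99.98 of 10000 random lists of equal size and matched mean expression. Only Wt1 and Tcf21 of this list exceeded the 99th percentile of the receptor genes, 5.48.

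Sclerotome and cartilage precursor genes, which mark the mesenchyme around the notochord, were higher in dorsal tissue as a group. Of 15 kept members, 3 were at least 2-fold higher there. Pax9, a paired-box factor of the sclerotome, was 4.35-fold higher at 6.15 against 4.02. Col2a1, the main cartilage collagen, was 2.96-fold higher at 5.54 against 3.98, and Uncx, a homeobox gene of the caudal sclerotome, at least 1.34-fold. Pax1 was measured at 3.73 in dorsal and 3.20 in ventral tissue, both at background. Hapln1, which encodes a link protein of the hyaluronan matrix, was the 1 member at least 2-fold higher in ventral tissue, by at least 5.05-fold. The median of the list lay at -0.46 relative to all kept genes, percentile 0.08 of the matched random lists. With no floor on expression, which brought in 4 more members near background, the median was -0.18 and the percentile 3.98. These were the only lists of 36 outside the central 95% of their random lists, where chance alone would place 1.8. The percentiles describe this pair of arrays and carry no replicate error.

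**Figure D2:**
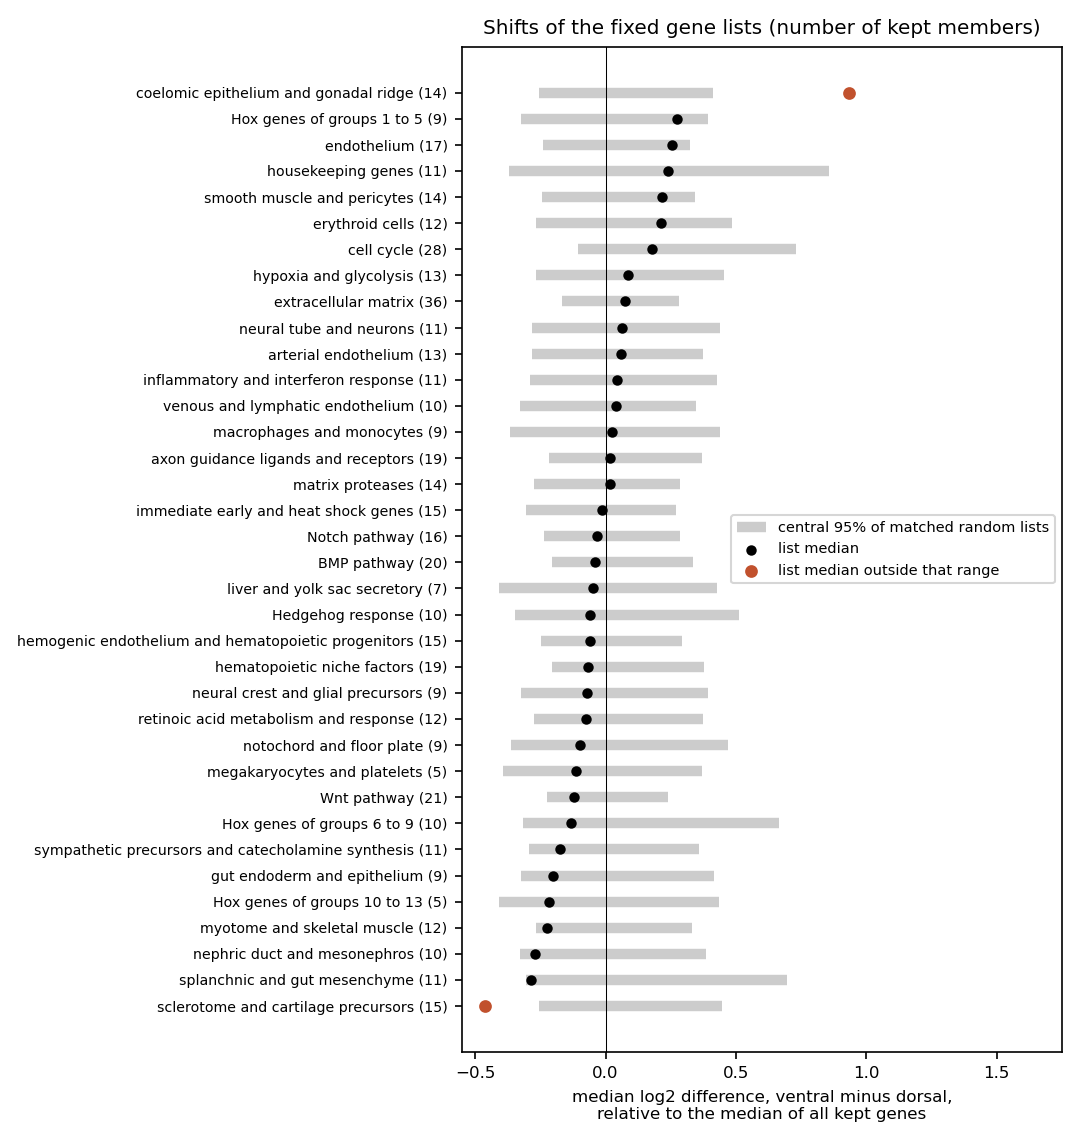
Median log2 difference (x axis, ventral minus dorsal, relative to the median of all kept genes) of each of the 36 gene lists with at least 3 kept members (y axis, number of kept members in brackets); grey bars span the central 95% of 10000 random lists matched on mean expression. Coelomic epithelium and gonadal ridge genes lie to the right of their bar at 0.93, sclerotome and cartilage precursor genes to the left at -0.46, and the other lists within theirs.

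Notochord and Hedgehog genes bore on the same dorsal position, and few of them differed. Shh, the ligand made by the notochord, was at least 2.30-fold higher in dorsal tissue, at 5.12 against 3.91, and Noto, a notochord homeobox gene, was higher there at 4.24 against 3.22. The other 7 of 9 kept notochord and floor plate genes were within 2-fold, and the list lay at percentile 34.0. Of 10 kept Hedgehog response genes Ptch1 was the only one at least 2-fold higher in dorsal tissue and Gli3, a mainly repressive Hedgehog transcription factor, the only one at least 2-fold higher in ventral tissue, by 3.48-fold, and the list lay at percentile 36.5. Foxf2, a forkhead factor of gut mesenchyme, was at least 9.48-fold higher in dorsal tissue, at 7.16 against 3.14. It was the only one of 11 kept genes of splanchnic and gut mesenchyme at least 2-fold higher there, and Bmp4 the only one at least 2-fold higher in ventral tissue. That list lay at percentile 3.18 by its median and at 1.44 by its mean. Foxf1 was at background on both arrays, at 3.76 and 3.45. In the myotome list Pax7 was at least 1.20-fold higher in dorsal tissue, while Myog and Myf5, within 2-fold, had dorsal values of 4.56 and 4.43 against ventral values of 3.59 and 3.48. Des, also within 2-fold, went the other way, at 4.54 in ventral against 3.55 in dorsal tissue. That list lay at percentile 4.92.

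Among 19 kept candidate niche factors, genes with published or proposed roles in supporting hematopoietic stem cells, 2 were at least 2-fold higher in ventral tissue, Ptn and Kitl. Kitl, which encodes stem cell factor, was measured at 7.47 in ventral and 2.56 in dorsal tissue, a difference of at least 11.7-fold. Cxcl12 and Igf2, the growth factor insulin-like growth factor 2, were at least 2-fold higher in dorsal tissue, Igf2 by 2.57-fold. The other 15 were within 2-fold, and the list as a whole lay at percentile 20.2. In the BMP pathway 3 of 20 kept genes were at least 2-fold higher in ventral tissue: Bmp5, Bmp4, at least 3.07-fold at 5.54 against 3.83, and Smad6, an inhibitory Smad, at least 3.10-fold. Another 3 were at least 2-fold higher in dorsal tissue, among them Id3, a BMP target gene, by 7.55-fold at 8.87 against 5.95. The other Id genes of the list were within 2-fold and not of 1 direction. Id1 and Id2 were higher in ventral tissue, at 4.78 against 4.01 and 7.42 against 6.75. Id4 was higher in dorsal tissue, at 4.09 against 3.58. Nog, the BMP antagonist noggin, was at background on both arrays, at 3.43 and 3.26. The BMP list lay at percentile 26.1.

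Markers of endothelium included 3 of 17 kept genes at least 2-fold higher in ventral tissue and none in dorsal tissue. Cdh5, which encodes VE-cadherin, was 5.34-fold higher at 6.64 against 4.22, Emcn, an endothelial sialomucin, at least 2.34-fold, and Kdr, the VEGF receptor, at least 1.88-fold. Pecam1 was 1.96-fold higher in ventral tissue. The list lay at percentile 94.3, inside the central 95% of its random lists. Arterial genes were at percentile 63.8, with 2 of 13 kept genes at least 2-fold higher in dorsal tissue and none in ventral tissue; 1 of them was Hey1, a Notch target, 3.30-fold higher at 7.49 against 5.77. Of 10 kept venous and lymphatic genes, Nr2f2, a venous and mesenchymal nuclear receptor, was the only one at least 2-fold apart, at 3.83-fold higher in ventral tissue, and that list lay at percentile 68.8. Genes of smooth muscle and pericytes had 4 of 14 kept members at least 2-fold higher in ventral tissue and none in dorsal tissue, with the list at percentile 89.8 by its median and 98.3 by its mean. Cnn1, the smooth muscle calponin, was at least 7.44-fold higher at 6.81 against 2.85, Actg2, enteric smooth muscle actin, 3.75-fold, and Acta2, alpha smooth muscle actin, 2.23-fold at 6.31 against 5.15. Acta2 was below 2-fold after quantile normalization of the 2 columns, at 0.87 on the log2 scale.

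Among regulators of blood stem cell emergence, Runx1, Gfi1 and Kit were near background in both tissues. Runx1, the transcription factor required for the emergence of blood stem cells, was measured at 3.68 in dorsal and 3.23 in ventral tissue, Gfi1 at 3.06 and 2.53, and Kit, the receptor of stem cell factor, at 3.07 on both arrays, all under the receptor genes' 95th percentile. A difference between the tissues in these genes was not detectable at this signal. Gfi1b, the paralog of Gfi1, was above background on both arrays, at 4.66 in dorsal and 5.28 in ventral tissue, and within 2-fold. Of 15 kept genes of hemogenic endothelium and hematopoietic progenitors, Cbfb, the widely expressed partner of Runx1, was the only one at least 2-fold apart, at least 3.48-fold higher in ventral tissue. Mecom, a transcription factor of blood stem cells, was above background in ventral tissue alone, at 4.59 against 3.76. That list lay at percentile 33.9. Of 12 kept erythroid genes, 4 exceeded the receptor genes' 99th percentile on at least 1 array. The embryonic globins Hbb-y, Hbb-bh1 and Hba-x, chosen after their values were seen, were at 12.01, 11.46 and 12.11 in dorsal tissue, with ventral minus dorsal differences of -0.01, 0.05 and -0.30 on the log2 scale. Globin genes have near-identical copies whose probes may share signal. The erythroid list lay at percentile 77.2, with Klf1, an erythroid transcription factor, 2.14-fold higher in dorsal tissue and the other 11 within 2-fold. Of 9 kept macrophage genes and 5 kept platelet genes none was at least 2-fold apart, and these lists lay at percentiles 61.6 and 40.0. All of these platelet genes and most of the macrophage genes were at background on both arrays, where a difference was not detectable.

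**Figure D3:**
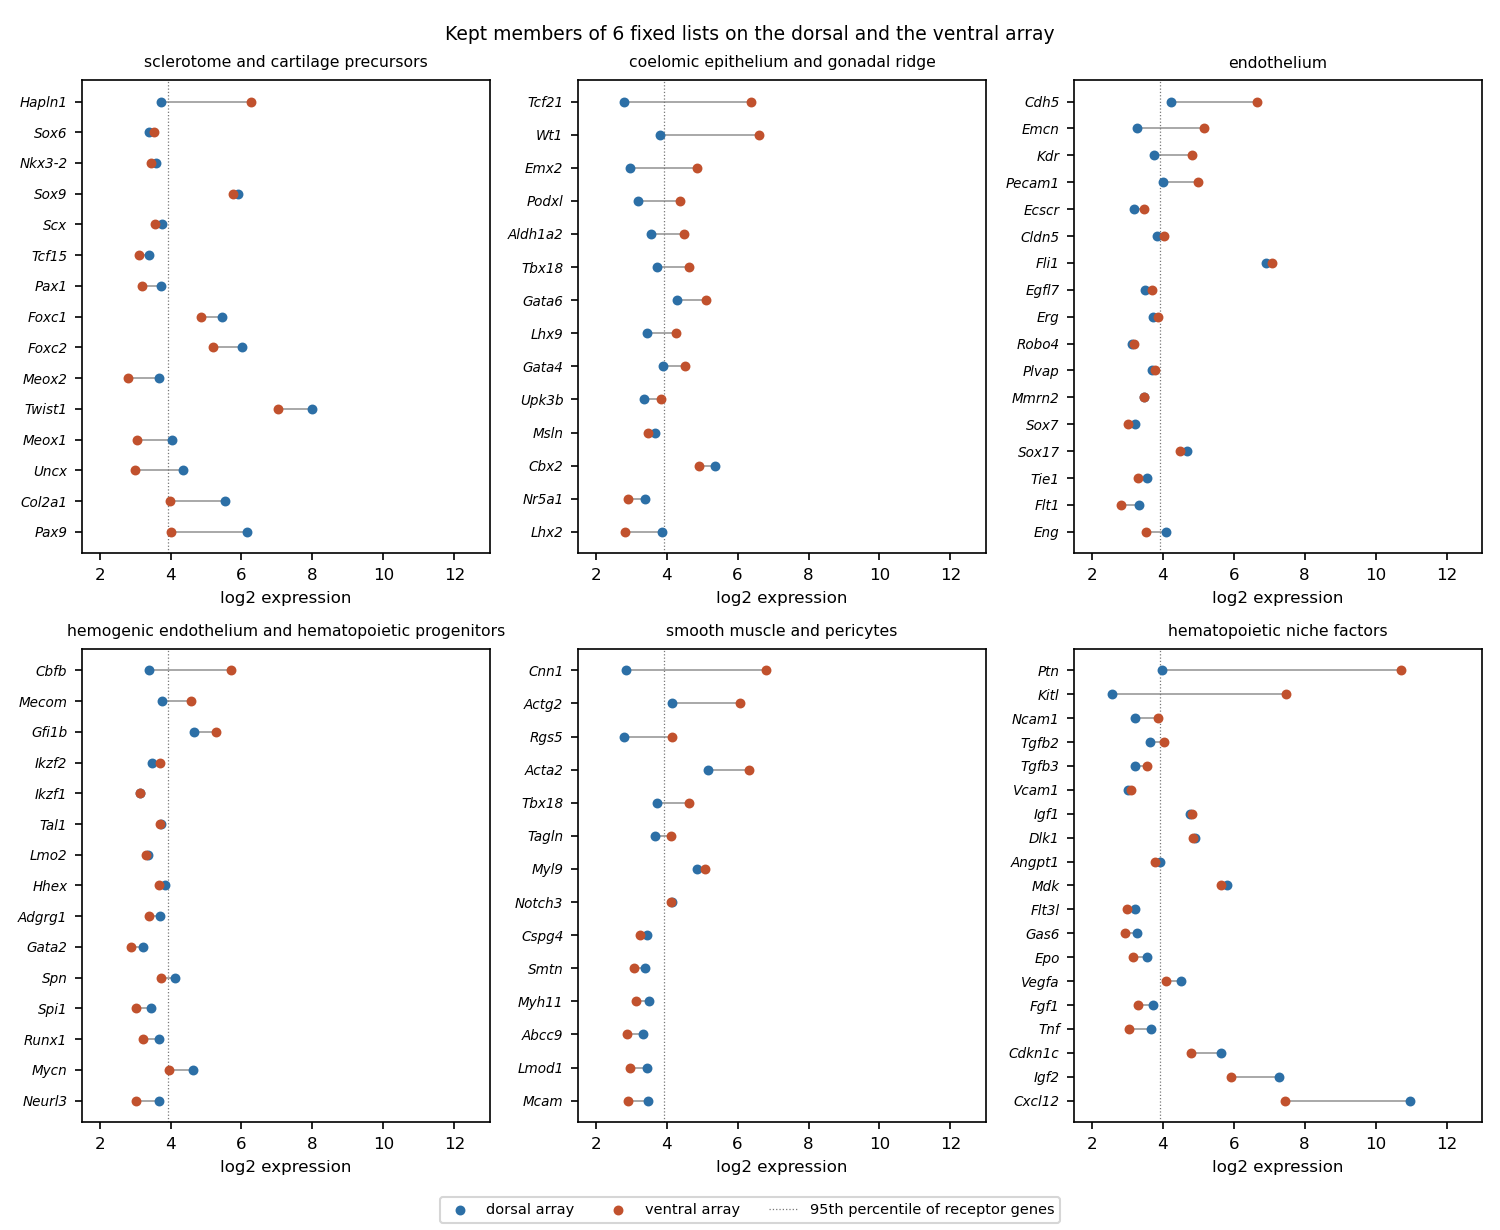
Log2 expression (x axis) of the kept members (y axis, ordered by their difference) of 6 gene lists on the dorsal array (blue) and the ventral array (red), with 1 value per array; the dotted line is the 95th percentile of the receptor genes, 3.92. Wt1 and Tcf21 reach 6.61 and 6.38 on the ventral array, Pax9 reaches 6.15 on the dorsal array, and Runx1 lies left of the dotted line on both.

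Extracellular matrix genes were mixed, with 4 of 36 kept members at least 2-fold higher in ventral tissue and 1 in dorsal tissue, and the list at percentile 65.7. Tnc, the matrix protein tenascin C, was at least 3.47-fold higher in ventral tissue and Tgfbi, another secreted matrix protein, at least 1.71-fold, beside Postn and Sparc. Lum, the proteoglycan lumican, was at least 1.89-fold higher in dorsal tissue. Fn1 and Vcan, abundant on both arrays, were within 2-fold, at 8.70 and 9.26 in dorsal and 9.16 and 8.69 in ventral tissue. Of the matrix proteases, Mmp16 was at least 3.04-fold and Mmp14 2.61-fold higher in ventral tissue, and the list lay at percentile 60.4. Axon guidance genes had 5 of 19 kept members at least 2-fold higher in ventral tissue and 2 in dorsal tissue, at percentile 43.7. Epha7, an ephrin receptor, was at least 6.61-fold higher in ventral tissue, Unc5c, a netrin receptor, at least 5.42-fold, and Robo1, a Slit receptor, at least 4.37-fold. Ifitm3, an interferon-induced membrane protein, was 8.79-fold higher in ventral tissue, while the inflammatory and interferon list lay at percentile 55.4.

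Neural, neural crest and sympathetic lists lay within the range of their random lists. Of 11 kept neural tube genes 2 were at least 2-fold higher in ventral and 1 in dorsal tissue, and of 9 kept neural crest genes 1 in each. Nefm, the medium neurofilament, was 6.67-fold higher in ventral tissue at 8.19 against 5.45, whereas Tubb3, neuronal tubulin, was 2.21-fold higher in dorsal tissue. Fabp7, a fatty acid-binding protein of glial precursors, was 3.86-fold higher in dorsal tissue at 8.15 against 6.20. The neural tube, neural crest and sympathetic lists lay at percentiles 57.9, 32.4 and 13.2. Gata3 was measured at 3.80 and 3.46 and Th, the first enzyme of catecholamine synthesis, at 3.91 and 3.28 in dorsal and ventral tissue, all at background. Lists of nephric duct, gut endoderm and liver genes lay at percentiles 5.53, 9.57 and 51.1, with Ttr, the transport protein transthyretin, 5.93-fold higher in dorsal tissue. In the Wnt list none of 21 kept genes was at least 2-fold apart, but most were at background on both arrays. Of 16 kept genes in the Notch list, Hes1, a Notch target, was 2.71-fold higher in ventral tissue, and 2 were at least 2-fold higher in dorsal tissue: Hey1, by 3.30-fold, and Jag2, a Notch ligand, with both levels, 3.80 and 2.69, at background. In the retinoic acid list Dhrs3, a retinaldehyde reductase, was at least 2.49-fold higher in ventral tissue. These 3 lists lay at percentiles 14.9, 42.8 and 27.4.

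Hox genes, whose combination marks the level along the body axis, were close in both pieces. Of 24 kept Hox genes Hoxd8 was 2.54-fold higher in ventral tissue and Hoxb8 was higher in dorsal tissue, at 3.97 against 2.78, and the other 22 were within 2-fold. Groups 1 to 5, 6 to 9 and 10 to 13 lay at percentiles 92.9, 14.5 and 19.0, and the last of these at 0.47 when no floor was set. Cell cycle genes were well detected, 23 of 28 above the receptor genes' 99th percentile, and 26 of the 28 were within 2-fold. The list lay at percentile 27.0. Nusap1, a spindle protein, was 5.79-fold higher in dorsal and Bub1b, a checkpoint kinase, 2.43-fold higher in ventral tissue. Immediate early and heat shock genes, read as signs of handling, lay at percentile 58.2 with none of 15 at least 2-fold apart, and the hypoxia and glycolysis list at percentile 60.0 with none of 13. Most of the immediate early and heat shock genes were at background on both arrays, so they are a weak check of handling. Commonly used reference genes were not all level: of 11 kept, Actb was 2.44-fold higher in dorsal tissue, and 2 were at least 2-fold higher in ventral tissue. These were B2m, by 3.50-fold, and Gusb, with both levels, 2.43 in dorsal and 3.54 in ventral tissue, at background. The list of reference genes lay at percentile 61.6. Gapdh, also on that list, fell under the floor at 2.12 in dorsal and 2.05 in ventral tissue. Both values were below the receptor genes' medians of 2.40 and 2.28. A level at background on these arrays therefore need not mean that a gene is silent. Xist was at 9.86 and 10.21, and the Y-linked genes Kdm5d, Uty and Eif2s3y were at background on both arrays.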

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

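The settings chosen after seeing the data were the floor at the receptor genes' 99th percentile, the loess on genomic span and random lists matched on span. No paired analysis was possible because each tissue has 1 array and the tissues share a single replicate number, and leaving out a replicate was not possible for the same reason. Alternatives on combining features of a gene were not run, since no gene has more than 1. The counts of genes at least 2-fold apart, 1320 and 682 (ventral and dorsal, as in each pair below), stayed within 1.5 times under quantile normalization (1157 and 799), centring (1527 and 527), loess on level, loess on genomic span, no floor, a floor at the 75th percentile and the removal of predicted genes. They became 792 and 335 with a floor at the receptor genes' 99th percentile, 2286 and 2099 at a threshold of 1.5-fold, and 393 and 131 at 4-fold; the share in ventral tissue was 52.1% at 1.5-fold and 75% at 4-fold. The Pearson correlation of the arrays was 0.891 over all genes and 0.831 over kept genes. It was 0.602 over genes above the receptor genes' 99th percentile on at least 1 array. Of the 84 named genes at 2-fold or more, 6 were below 2-fold in at least 1 of quantile normalization, centring and loess on level: Noto, Pax7, Jag2, Klf1, Acta2 and Nfkbia. The coelomic list stood apart in 10 of 10 settings that gave it a percentile, from 99.65 to 100; a floor at the receptor genes' 99th percentile left 2 members and gave none. The sclerotome list stood apart in 10 of 11 settings, and its median was -0.18 with no floor (percentile 3.98), -0.99 with the floor at the 75th percentile and -1.24 with the floor at the receptor genes' 99th percentile. Centring cannot move list medians, which are relative to all genes, and is left out of these counts. Over the lists and the alternatives that could move a median, 233 medians moved by less than 0.5 of the width of the random lists' central 95% range and kept their side of the bounds, 7 passed a bound, 1 no longer passed it, 19 moved otherwise and 0 reversed. Lists that stood apart under an alternative alone were Hox groups 10 to 13 with no floor (-0.27), myotome (-0.65) and smooth muscle (1.0) with the floor at the 75th percentile, nephric duct with the span trend removed (-0.35), gut mesenchyme (-0.37) and smooth muscle (0.66) by the mean, and notochord without genes of another list (-0.91, over 3 genes). Medians that moved without standing apart were, with the floor at the 75th percentile, endothelium (0.58), hemogenic endothelium (0.61), BMP (0.28), matrix (0.31), proteases (0.94) and inflammation (0.65); with the floor at the receptor genes' 99th percentile, gut mesenchyme (-0.96), erythroid (-0.32), smooth muscle (1.56), niche factors (-0.86), BMP (0.85), axon guidance (1.95), cell cycle (-0.34) and housekeeping (-0.63); by the mean, niche factors (0.36), BMP (0.29) and axon guidance (0.53). The higher floors keep fewer genes by construction; other causes were not tested. Signal near background limits most lists: only 2628 genes passed the receptor genes' 99th percentile on either array.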

Other observations

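Gene families were also examined after the data were seen, by symbol, 14 in all. Some overlap the fixed lists, such as the collagens and the Hox genes. Because they were defined after the values were seen, their percentiles are not independent support. The vesicle transport family holds Rab4a and Trappc6b, already among the 12 greatest excesses in ventral tissue. Of all 13982 kept genes, 1320 were at least 2-fold higher in ventral and 682 in dorsal tissue. Genes of vesicle transport (Rab, Vps, Trappc, Sec and coatomer genes) had 22 of 121 kept members at least 2-fold higher in ventral and 3 in dorsal tissue, at percentile 98.4 of matched random lists, and between 19 and 25 against 2 to 5 under quantile normalization, centring and loess on level. Splicing factors had 11 of 40 higher in ventral and 3 in dorsal tissue, percentile 98.1, with 6 against 4 after quantile normalization, 16 against 2 with differences centred and 8 against 4 under loess on level. With the trend with genomic span removed these percentiles were 92.5 and 96.7. Cytosolic ribosomal protein genes had 4 higher in ventral and 9 in dorsal tissue of 53, percentile 3.05, a split that became 6 and 6 when differences were centred. Gamma protocadherins, whose transcripts share constant exons so that their values are not independent, had 5 of 15 at least 2-fold higher in each tissue, percentile 82.3. The percentiles of the other families that were tried, mitochondrial ribosomal, respiratory chain, proteasome, translation initiation, polymerase II, histone, Zfp, collagen, solute carrier and Hox genes, lay between 10.1 and 94.5. These percentiles depended on the setting: with a floor at the receptor genes' 99th percentile, vesicle transport and Zfp genes lay at 99.2, mitochondrial ribosomal genes at 0.97, histones at 1.35, gamma protocadherins at 0.02 and splicing factors at 81.9. With the span trend removed collagens lay at 0.38 and cytosolic ribosomal genes at 17.2.

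For the explanations below, the tests of background noise and of blood content were chosen only after the result was seen. The others were written before their result was seen. Among these, the test of amplification loss used machinery genes from families that were defined after the values were seen. More genes were at least 2-fold higher in ventral than in dorsal tissue, 1320 against 682, a ratio of 1.94. Noise of genes near background is argued against as the whole cause, which would bring the ratio close to 1 above background: it was 1.71 (95% interval 1.37 to 2.15, over genes, which are not independent) with both arrays above the receptor genes' 99th percentile, 1.99 (1.69 to 2.36) with their mean above it, and 2.08 (1.81 to 2.38) and 2.22 (1.99 to 2.47) likewise for the 95th percentile. The limit asked of these ratios was set after they were seen and was less strict than that for quantile normalization below. They were counted on the deposited values, so they still hold any effect of different value distributions. Different value distributions cannot be told apart from an effect of tissue: quantile normalization of the columns brought the ratio to 1.45 (1.32 to 1.59), between the bounds set for either reading. The ratio was higher for protein-coding genes of longer genomic span: in 3 groups of 3975 genes by span it was 0.991 in the shortest (233 against 235), 2.36 in the middle and 3.88 in the longest (512 against 132). Removing a loess on span left 2.03, but this moves medians and not tails, and the ratio still went from 1.45 to 2.45 between the shortest and longest groups, so a technical trend linked to gene length or base composition remains open beside the untested difference of tissue.

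Of 174 genes at least 8-fold apart, 126 were higher in ventral and 48 in dorsal tissue. In 118 of them (67.8%) the lower array was at background, and in 163 it was under the receptor genes' 99th percentile. Loss of transcripts during amplification of picograms of RNA may contribute: if it struck any gene alike, genes of ubiquitous machinery should show such gaps at 0.5 times the rate of others or more. Among 211 machinery genes above the receptor genes' 99th percentile, 8 were at least 8-fold apart, 0.487 times the rate of genes matched on the higher array (interval 0.333 to 0.8 and percentile 0.575 from random lists), so that they had fewer such gaps than matched genes, just under that bound and above the 0.25 set for excluding it. For expression restricted to 1 tissue, 3 of 29 marker genes were at least 8-fold apart, 1.93 times the matched rate, at percentile 86.0, too few genes to decide. Both explanations stay open, and the gaps in genes such as Uchl3, Rab4a and Hdac1 would need a second pair of arrays. The same holds for the niche factors Kitl and Ptn, whose dorsal levels were at background and just above it.

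The coelomic epithelium and gonadal ridge list was higher in ventral tissue by 0.93. The share of matched random lists with as high a median, doubled for either direction and times 36 lists, was 0.0144, and 0.0576 for the sclerotome list as low; this describes the draw of genes on these arrays, and chance between embryos or cuts was not testable. The coelomic list still stood apart when genomic span was allowed for. Its percentile was 99.97 with the trend removed and 99.97 with random lists matched on span. Without genes that another list also holds it was 99.65. These percentiles do not allow for the choice of this list, which was picked for standing apart on these same values. The loess on span also moves medians and not tails. How much the trend with genomic span added to the shift therefore stays open. A lower share of blood cells in the ventral piece would raise the markers of all other cell types alike. The coelomic median exceeded that of 144 markers of other cell types outside blood by 1.03 (95% interval over genes 0.22 to 1.41). The excess was 0.89 to 1.08 under quantile normalization, loess on level, no floor and the floor at the 75th percentile. This cannot decide, because the coelomic list was picked for standing apart on these same values, and the interval does not allow for that choice. The erythroid list decides nothing either, with medians of 0.213, -0.09 with loess on level and -0.32 with the floor at the receptor genes' 99th percentile. Blood content therefore stays open. So does how much of the body cavity lining each cut took in, which the design does not separate from a property of the tissue under the aorta.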
